A study of Homo sapiens with 2 samples.

How the data were processed

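Total RNA (1 ug per library) was extracted with Trizol from HES2 cells infected with scramble or Tfcp2l1 shRNA lentivirus, and libraries were sequenced on a BGISEQ-500, per the labels' protocols. The labels also name standard Illumina protocols for library preparation. The submitters' processing notes name the human build hg19 and Bowtie 0.12.2. The read counter, the quantifier, the test, the strand setting and the filters are not given in the sources used here. Each group had 1 library, and the groups follow the infection named in the labels.

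The data were the authors' deposited table of 2005 genes, which holds a level per library, a log2 ratio, a p-value, a false discovery rate, a gene length and a call for each gene. Its header calls the levels expression only. They were read as FPKM, because the deposited values scale with inferred reads per kilobase and library size, and RPKM and FPKM cannot be told apart from the values. The lowest deposited FPKM is 0.01, a floor that stands for values at or near 0, and 76 genes are at it in the scramble library and 26 in the knockdown library. The deposited log2 ratio equals log2 of the knockdown level over the scramble level. Of the deposited genes, 144 are loci without a gene symbol, 79 of them higher and 65 lower. In the authors' deposited table the largest false discovery rate is 0.000990 and the smallest size of a log2 ratio is 1, so the table holds only genes that passed limits on both.

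The number of genes the authors tested was inferred from their p-values and false discovery rates. The ratio of the p-value to the rate gives whole ranks for 18489 genes, with a largest deviation of 6.2e-09. The listed genes are 5.86% (higher) and 4.98% (lower) of those tested. The highest rank among listed genes is 7704.

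Reads were inferred too, since the authors' deposited table holds no counts. The p-values of genes at the floor in the scramble library follow whole steps for 55 of 62 genes, which gives a depth ratio of 1.034 (scramble over knockdown), and the FPKM values give 1.032. For each gene, pairs of whole reads were sought that fit both FPKM values and the p-value of a Poisson test of 2 libraries (Audic and Claverie, doubled smaller tail), within 0.0002 on the natural log of p. Of 1926 genes with a p-value above 0, 1486 (77.2%) had such a pair, 1471 of them exactly 1, and 440 had none. Another 79 have a p-value printed as 0. Reads of the genes without a pair were estimated from the FPKM, and these include most of the highest ratios. Depth came from 659 genes, with a length offset of 69 bases. On simulated tables of 2005 genes, 98.1% of genes with a p-value above 0 had a pair, and 99.3% of the pairs were exactly those drawn.

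Log2 ratios were computed from FPKM with a pseudocount of 0.1, which understates the ratios of genes at low levels. Genes were counted as at least 2-fold higher or lower if they were at 1 FPKM or more in at least 1 library. Ratios of inferred reads, scaled by depth, were given exact (Clopper-Pearson) 95% intervals of the conditional binomial share, which cover counting error only, since reads without molecular identifiers are not independent molecules. Where a library held 0 reads, the ratio was taken against a floor of 3 reads per library and given as a fold against that floor. This fold leaves out counting error in the other library and lies above the lower limit of the 95% interval. Where it is given for a named gene, that lower limit stands beside it. On simulated reads the true ratio was inside the interval for 95.0% of 200 changed genes. No p-value of the conditions was computed, since there was 1 library per group. The count models written into the plan were not used because the authors' table holds FPKM and no counts.

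Before the data were examined, 30 gene lists with 588 members were fixed. For each list with at least 3 members at 0.5 FPKM or more, the median log2 ratio was compared with 10000 random lists of the same size, drawn from listed genes in 20 bins of mean log level. Because the table holds only genes that passed the authors' limits, the percentile describes direction and size among selected genes. On simulated data, 6 of 100 lists of 15 genes without a shift fell in the lowest or the highest 2.5%, and 28 of 50 lists shifted by 2 on the log2 scale fell in the highest 2.5%, so a list outside these ends is not shown to be unshifted. List medians computed with genes of 0 reads at their fold against the floor were the same.

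The rule for named genes, also fixed before, takes TFCP2L1, POU5F1, SOX2 and NANOG, the 12 highest and the 12 lowest log2 ratios among the counted genes with a symbol, and up to 3 of the highest and 3 of the lowest members of each list. Further list members and the genes of the closing observations were chosen after their values were seen. Values of some genes that the rule takes are not reported here. Sequence sharing was measured as the percent of 31-base words of a gene's longest transcript that occur in transcripts of another gene, in GENCODE 29, for 1810 of 1861 symbols (97.3%). That annotation is of another build than the authors' hg19, and the table gives no positions, so no coordinates are given. The alternatives tried were a pseudocount of 1 FPKM, the deposited log2 ratio, other level minimums (none and 5 FPKM for counts of genes, none and 1 FPKM for lists), ratios of 1.5 and 4, unmatched random lists, a mean in place of the median and a background without the members of other lists. Chosen after the data were seen were the inferred reads, the removal of genes with at least 50% shared words, and 3 further gene lists (motile cilia, organizer and axial mesoderm, and metallothioneins). Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.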

Results

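RNA was sequenced from HES2 cells, an established line of human embryonic stem cells, after infection with a lentivirus that carried either a scrambled control or a short hairpin RNA (shRNA) against TFCP2L1. TFCP2L1 is a transcription factor of the CP2 and grainyhead family, known as part of the pluripotency network of mouse embryonic stem cells. Both cultures were kept for 3 passages in medium with 10% KSR, with FGF2 and Activin A at 10 ng/ml each. There was 1 library per group, so no difference given here has a replicate check, and every comparison is between these 2 libraries. The values come from the authors' deposited table of 2005 genes, which holds 1084 genes higher and 921 genes lower in the knockdown library, each by at least 2-fold. Nothing is said here about the level of a gene with no row in that table. The libraries held about 23460000 (scramble) and 22740000 (knockdown) reads, as inferred from the deposited values, and the listed genes held 12 to 44043 reads over both libraries, with a median of 273. Levels are in FPKM, ratios are knockdown over scramble, and intervals are exact (Clopper-Pearson) 95% intervals that cover counting error only.

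The comparison asks how the transcripts of human embryonic stem cells differ when TFCP2L1 is targeted. TFCP2L1 itself (gene ID 29842) was at 3.19 FPKM in the scramble library and 0.33 FPKM in the knockdown library. Its inferred reads numbered 692 and 69, which made it 9.70-fold lower in the knockdown library (interval 7.56 to 12.6). The log2 ratio with a pseudocount of 0.1 FPKM was -2.94, and the authors' deposited table gives -3.27. The close relatives of TFCP2L1 (TFCP2, UBP1, GRHL1, GRHL2 and GRHL3, a list of 5) had no row in the table used here.

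The 12 genes with the highest log2 ratios were ranked with the pseudocount of 0.1 FPKM. Apart from NPPB, PRSS2 and CHRD, they are members of the primitive streak, endoderm or WNT target lists described further on. By the ratio of reads, SHH (286) and ANKRD1 (282), each on 1 scramble read, were above CER1 (131) and are on none of these lists. FGF17, an FGF ligand, was at 0.45 FPKM in the scramble library and 323 FPKM in the knockdown library, a ratio of 717 (interval 427 to 1311). FOXA2, an endoderm transcription factor, was at 0.05 and 56.5 FPKM, a ratio of 1044 on 3 scramble reads (interval 357 to 5067). SOX17, a further endoderm regulator, had no scramble reads and 26.6 FPKM in the knockdown library. Against the floor of 3 reads it was 475-fold higher (interval from 386 upward). EOMES (0.25 and 76.0 FPKM), GATA6 (0.06 and 28.7 FPKM), LHX1 (0.20 and 52.8 FPKM) and SP5 (0.23 and 59.2 FPKM) had ratios of 301, 501, 260 and 264. The secreted inhibitors CER1 (6.11 and 799 FPKM) and CHRD (0.54 and 79.4 FPKM) had ratios of 131 (interval 112 to 154) and 149 (interval 111 to 204). The WNT inhibitor DKK4, the natriuretic peptide gene NPPB and the trypsinogen gene PRSS2 had no scramble reads and were at 26.9, 50.8 and 21.4 FPKM in the knockdown library. Against the same floor they were 162, 255 and 131-fold higher (intervals from 132, 207 and 106 upward). Of the 31-base words of the PRSS2 transcript, 24.0% also occur in another gene, so its level is uncertain.

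TFCP2L1 was itself among the 12 genes with the lowest log2 ratios. CTGF, a secreted matricellular protein, was at 80.5 FPKM in the scramble library and 7.83 FPKM in the knockdown library, a ratio of 0.0976 (interval 0.0880 to 0.108). TXNIP, an inhibitor of thioredoxin and of glucose uptake, was at 223 and 28.1 FPKM, which made it 7.93-fold lower (interval 7.55 to 8.33). The metallothionein MT1G was at 22.7 and 1.49 FPKM, and its relative MT1H was at 2.98 FPKM with no knockdown reads. Against the floor of 3 reads MT1H was 7.41-fold lower (interval from 5.56 upward). PKD1L2 (7.33 and 0.77 FPKM), SCNN1G (2.06 and 0.06 FPKM), G0S2 (3.19 and 0.29 FPKM) and CRYBA4 (3.81 and 0.40 FPKM) had ratios of 0.106, 0.0310, 0.0913 and 0.118. AOC2 was at 1.05 FPKM with no knockdown reads, 20.3-fold lower against the floor (interval from 16.03 upward). SERF1A was at 7.96 FPKM with no knockdown reads, 68.6-fold lower against the floor (interval from 55.3 upward). SERF1A and MEF2B (3.77 and 0.18 FPKM) are uncertain, because 98.3% and 77.6% of their 31-base words also occur in another gene. MT1G (21.6%) and MT1H (25.6%) are uncertain for the same reason.

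By a rule of size, 819 genes were at least 2-fold higher and 710 at least 2-fold lower in the knockdown library, among the 1587 listed genes at 1 FPKM or more in at least 1 library. These 1529 genes are 76.3% of the authors' deposited table. The higher genes reached further from the scramble level than the lower ones: 240 against 107 genes passed 4-fold, 114 against 15 passed 8-fold, 62 against 4 passed 16-fold and 18 against 1 passed 64-fold. With the pseudocount of 0.1 FPKM, SERF1A and MT1H were the only lower genes with a symbol past 16-fold, and SERF1A was the one past 64-fold. Both are uncertain because of shared sequence. With a counting interval wholly beyond 2-fold, 595 genes were higher and 424 lower. With a pseudocount of 1 FPKM, 546 were higher and 364 lower.

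**Figure D1:**
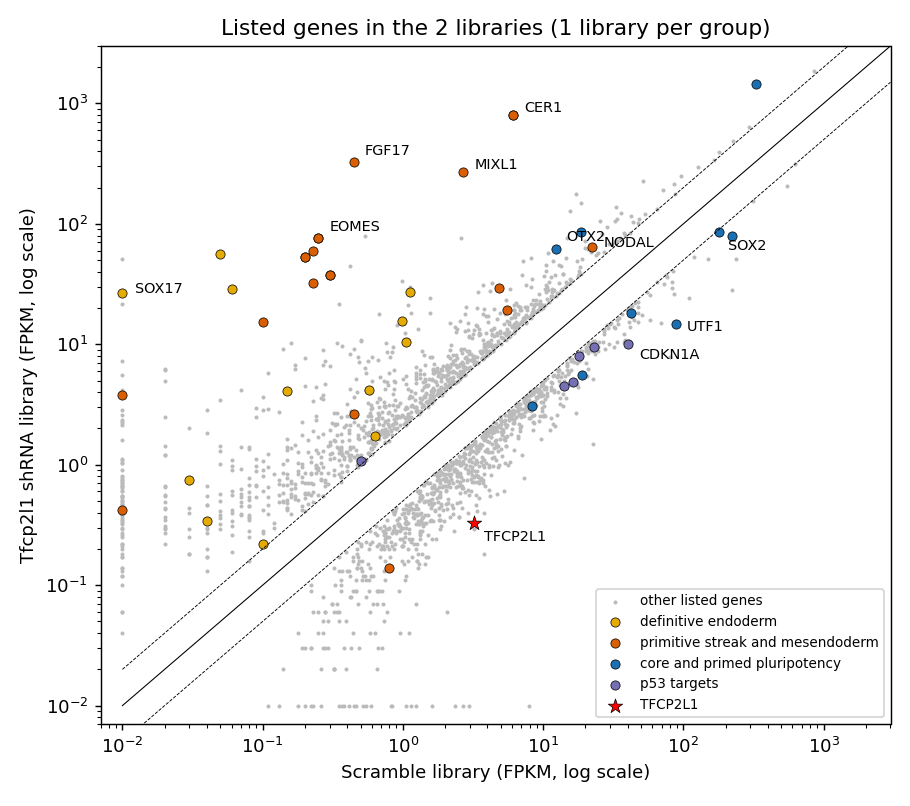
Level of each listed gene in the scramble library (x axis, FPKM, log scale) against the Tfcp2l1 shRNA library (y axis, FPKM, log scale), with the line of equal levels and dashed lines at 2-fold; genes in both the streak and the endoderm list are drawn in the streak colour. The empty band along the diagonal is where the table holds no genes, CER1 (6.11 and 799 FPKM) and FGF17 (0.45 and 323 FPKM) lie far above it, and TFCP2L1 (3.19 and 0.33 FPKM) lies below it.

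Among the lists fixed beforehand, those of the primitive streak and of the definitive endoderm had the highest median ratios. Of 19 primitive streak and mesendoderm genes, 16 were listed, 15 of them higher and 1 lower. The median log2 ratio was 6.55 over the 15 members at 0.5 FPKM or more, 6.41 over all 16, and 4.75 with a pseudocount of 1 FPKM. MIXL1 was at 2.70 and 267 FPKM (ratio 99.2, interval 83.1 to 119), T (brachyury) at 0.23 and 32.1 FPKM, and GSC at 0.30 and 37.5 FPKM. NODAL was already at 22.4 FPKM in the scramble library and was at 64.4 FPKM in the knockdown library, and WNT3 was at 5.50 and 19.2 FPKM. MESP2 was the member that was lower, at 0.80 and 0.14 FPKM. Of 20 definitive endoderm genes, 16 were listed and all 16 were higher. The median log2 ratio was 5.52 over the 14 members at 0.5 FPKM or more, 4.28 over all 16, and 4.25 with a pseudocount of 1 FPKM. CXCR4, a surface marker of definitive endoderm, was at 1.13 and 27.3 FPKM (ratio 24.3, interval 17.9 to 33.8), and HHEX was at 0.98 and 15.5 FPKM. The apolipoprotein gene APOB was closer to the scramble level, at 0.10 and 0.22 FPKM. The lists share EOMES, LHX1, CER1 and GSC, and together they hold 28 listed genes, 27 of them higher.

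Of 22 targets of WNT/beta-catenin signalling, 14 were listed, 13 higher and 1 lower. The median log2 ratio was 3.21, or 1.31 with a pseudocount of 1 FPKM and 4.21 with the ratios of the authors' deposited table. The direct feedback target AXIN2 was at 5.67 and 14.8 FPKM (ratio 2.61, interval 2.37 to 2.88, uncertain with 30.7% of its words in another gene), APCDD1 at 1.09 and 21.3 FPKM, and TCF7 at 6.34 and 13.8 FPKM. MYC was the lower member, at 47.2 and 20.4 FPKM. This list shares SP5, T, DKK1 and CDX1 with the primitive streak list.

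Pluripotency genes differed in both directions. SOX2 was at 180 FPKM in the scramble library and 86.1 FPKM in the knockdown library, a ratio of 0.478 (interval 0.462 to 0.495). POU5F1 and NANOG had no row in the table used here. Of 30 genes of the core and primed state, 9 were listed, 3 higher and 6 lower, with a median log2 ratio of -1.21. UTF1 was at 88.7 and 14.8 FPKM (ratio 0.168, interval 0.150 to 0.187), DPPA2 at 18.8 and 5.59 FPKM, PODXL at 222 and 79.1 FPKM, PRDM14 at 42.4 and 18.3 FPKM, and TERT at 8.39 and 3.09 FPKM. The higher members were OTX2 (12.3 and 62.2 FPKM), ZIC2 (18.7 and 85.5 FPKM) and the neuropeptide gene GAL (327 and 1455 FPKM). Of 25 genes of the naive state, 9 were listed, 6 higher and 3 lower. The median log2 ratio was 1.94 over the 8 members at 0.5 FPKM or more, 1.54 over all 9, and 1.13 with a pseudocount of 1 FPKM. FGF4 (1.56 and 24.4 FPKM), GBX2 (0.47 and 4.05 FPKM) and NR0B1 (no scramble reads and 0.90 FPKM) were higher, and KLF4 (2.49 and 0.81 FPKM), NLRP7 (2.44 and 0.73 FPKM) and TFAP2C (14.8 and 6.95 FPKM) were lower.

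**Figure D2:**
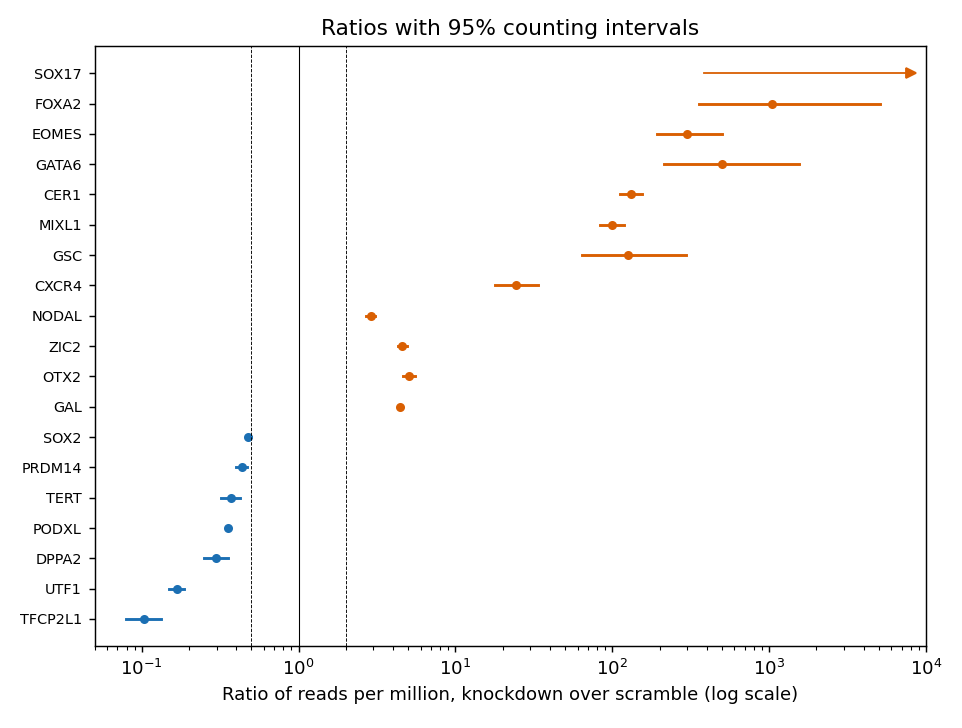
Ratio of depth-scaled reads in the knockdown library over the scramble library (x axis, log scale) for endoderm, streak and pluripotency genes and TFCP2L1, each a point with its 95% counting interval as a bar; the arrow marks SOX17, which had no scramble reads, and the lines mark equal levels and 2-fold. SOX2 (0.478) to UTF1 (0.168) span a range of lower ratios, and CER1 (131) and MIXL1 (99.2) lie far to the right.

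Of 20 p53 targets, 6 were listed, 5 lower and 1 higher, with a median log2 ratio of -1.45. The cell cycle inhibitor CDKN1A was at 40.5 and 10.0 FPKM (ratio 0.248, interval 0.224 to 0.274), SESN1 at 16.4 and 4.85 FPKM, and GDF15 at 14.2 and 4.47 FPKM, while SPATA18 was higher at 0.50 and 1.08 FPKM. Of 19 genes of the ER stress and amino acid response, 5 were listed and all 5 were lower, among them CHAC1 (22.6 and 5.14 FPKM) and DDIT3 (8.28 and 2.98 FPKM), with a median log2 ratio of -1.29. Of 25 hypoxia and glycolysis genes, 5 were listed, 2 higher and 3 lower, with a median log2 ratio of -1.47. PDK1 was at 11.8 and 48.9 FPKM and ALDOC at 50.5 and 17.6 FPKM.

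Signalling and lineage lists outside the streak and endoderm had fewer listed members. All 3 listed of 12 Activin/NODAL targets were higher, among them CER1 and NODAL, as were all 4 listed of 24 mesoderm genes, among them TAGLN at 51.5 and 226 FPKM. Of 17 FGF/ERK targets 5 were higher and 1 lower, with DUSP4 at 1.00 and 5.16 FPKM. Of 14 BMP targets 3 were higher and 1 lower, with ID3 at 8.25 and 52.0 FPKM. Of 18 YAP/TEAD targets 5 were higher and 2 lower. ANKRD1 was at 0.02 and 6.22 FPKM, on 1 scramble read. The lower members were CYR61 (33.4 and 10.5 FPKM) and CTGF (80.5 and 7.83 FPKM). Of 27 mesenchyme and fibroblast genes 8 were higher and 2 lower, with CDH2 at 19.7 and 62.8 FPKM, VIM at 85.6 and 215 FPKM, and COL1A1 lower at 110 and 24.4 FPKM. Neuroectoderm genes split evenly, with 2 of 26 higher (NES, 95.9 and 252 FPKM, and SIX3) and 2 lower (SOX3, 24.4 and 8.82 FPKM, and DLL1). Neural crest genes had 2 of 16 higher and 4 lower, with NGFR at 8.60 and 2.60 FPKM, and germ cell genes had 2 of 13 higher and 4 lower, the higher ones being SOX17 and PRDM1. Trophectoderm and amnion genes had 1 of 22 higher (KRT8, 293 and 640 FPKM, with 35.3% of its words in another gene) and 2 lower, endothelium and blood genes 1 of 16 higher and 2 lower (TIE1, 5.39 and 1.04 FPKM), and interferon response genes 2 of 24 higher and 2 lower. The higher interferon genes, IRF9 and IFITM1, are uncertain, with 100% and 45.9% of their words in another gene.

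The remaining lists had almost no listed members. Of 28 proliferation genes UHRF1 was listed, at 9.47 and 23.1 FPKM, with 32.5% of its words in another gene. Of 21 epithelial junction genes DSP was higher (20.9 and 61.4 FPKM) and CLDN3 lower (20.2 and 6.94 FPKM), and of 7 cell cycle inhibitors CDKN2B was higher (no scramble reads and 0.53 FPKM) and CDKN1A lower. HSPA1A (13.6 and 28.7 FPKM, uncertain with 74.3% of its words in another gene) was the listed member of 11 heat shock genes and NDUFB3 (32.8 and 13.8 FPKM) of 23 oxidative phosphorylation genes. Of 21 cholesterol synthesis genes, 1 was listed and lower. None of 34 ribosomal protein genes, 14 replication-dependent histone genes and 15 housekeeping genes on the lists had a row in the table used here. Outside these lists, RPS28, a ribosomal protein gene singled out after its value was seen, was at 630 and 313 FPKM, and the histone genes HIST1H1A (2.93 and 0.86 FPKM) and HIST1H2AC (10.1 and 3.07 FPKM), found in the same way, were lower too.

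**Figure D3:**
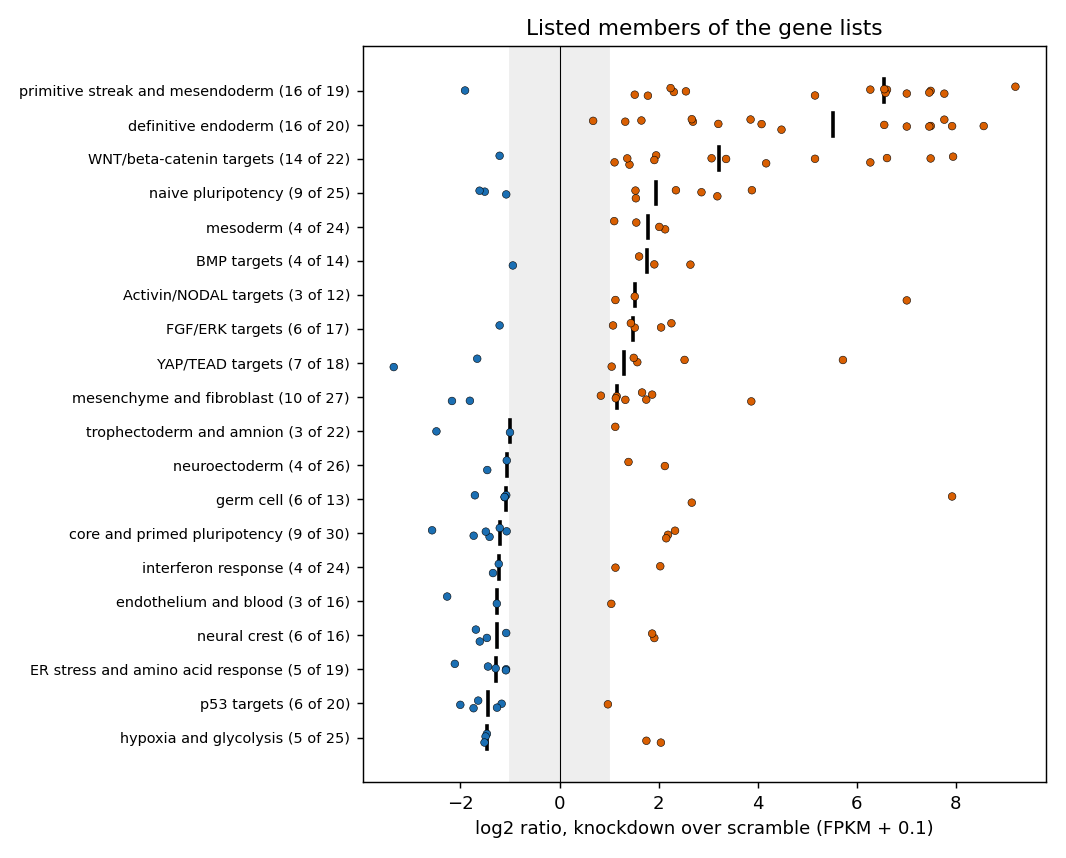
Log2 ratio of each listed member (x axis, knockdown over scramble, FPKM plus 0.1) by gene list (y axis, with listed members of all members), orange where higher and blue where lower, with black bars at the medians of the members used and the grey band within 2-fold. The streak (median 6.55), endoderm (5.52) and WNT target (3.21) lists lie farthest to the right. Hypoxia and glycolysis (-1.47) and the p53 targets (-1.45) have the lowest medians.

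Each list median was set against 10000 random lists of listed genes matched on level, as a description of these libraries within an already selected table. Of the 20 lists with at least 3 usable members, 5 had a median in the lowest or the highest 2.5% of random lists. The primitive streak, definitive endoderm and WNT target lists were at a percentile of 100, the naive list at 98.3 and the p53 targets at 0.990. The core and primed list was at 2.61, hypoxia and glycolysis at 3.78, ER stress at 4.45 and neural crest at 10.2. Germ cell (31.5), neuroectoderm (31.8), interferon (25.6), endothelium and blood (26.4), trophectoderm (47.1) and mesenchyme (69.5) were nearer the middle, and YAP/TEAD (84.8), Activin/NODAL (88.0), BMP (89.96), FGF/ERK (92.1) and mesoderm (93.3) nearer the top. The naive list was inside these limits under 4 other settings, with percentiles of 89.2 to 96.8, and the core and primed list ranged from 2.15 to 12.6 over its settings (8.97 with the mean, where its value was -0.31). Hypoxia and glycolysis was at 36.5 with a pseudocount of 1 FPKM (median -0.64) and at 35.1 with the mean (-0.13). The p53 list was at 3.67 against random lists not matched on level.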

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

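The tests of swapped labels, of counting noise over all fixed members, of a difference between the cultures and of a lost share of cells were chosen after the result was seen, while the bounds for counting noise over listed members and for shared sequence were set before.

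Loci without a gene symbol stood outside the comparisons of named genes, and 5 of them were at the floor in the scramble library and at 1 FPKM or more in the knockdown library. A locus of 272 bases was at 3.97 FPKM (6.55-fold higher against the floor of 3 reads) and one of 3352 bases at 2.83 FPKM (73.1-fold). Those of 1273, 535 and 546 bases were at 2.36, 2.32 and 1.59 FPKM (22.4, 8.62 and 6.21-fold). These folds leave out counting error in the knockdown library.

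Primitive streak and endoderm genes were far higher in the knockdown library. If the shRNA set the level of TFCP2L1, swapped labels would make it higher in the library labelled knockdown. Its log2 ratio was -2.94, which on that condition argues against a swap of the 2 libraries. If differentiation can lower TFCP2L1, which was not tested, this ratio cannot exclude a swap. For counting noise, 25 of the 28 listed members (89.3%) had an interval wholly above 2, just under the 90% set beforehand, and after that miss 92.6% was counted over the 27 higher members, which selects on the outcome, and 71.4% (exact interval 53.7 to 85.4) over all 35 members fixed beforehand, with or without a row; counting error alone would give at most 2.5%, which argues against noise as the cause of the whole pattern and leaves it open for the other 3 listed members. A difference between the 2 cultures that does not come from the shRNA may give the same pattern, and with 1 library per group it cannot be told apart from the knockdown. Effects of the shRNA on other transcripts, and a lower TFCP2L1 level as a result of differentiation, were not tested, so a response to less TFCP2L1 stays a hypothesis.

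The 6 lower genes of the core and primed pluripotency list had unequal ratios. The lower bound of SOX2 (0.462) was 2.47 times the upper bound of UTF1 (0.187). Loss of a share of undifferentiated cells that carry all of each transcript would give the 6 genes a common ratio. These intervals cover counting error only, and with 1 library per group the variation of each gene between cultures is unknown, so that loss is neither excluded nor shown.

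Genes at the floor in a library may be there because reads were assigned to another gene of the same sequence. Of the 19 knockdown-floor genes with a known sequence, 6 (31.6%, exact interval 12.6 to 56.6) had at least 50% of their words in another gene, against 5.53% (interval 4.06 to 7.33) of the other 814 lower genes, which met the bound of 25 percentage points set beforehand. Of the 62 scramble-floor genes, 15 (24.2%, interval 14.2 to 36.7) did, against 5.46% of 915, a difference of 18.7 points that lies between the bounds, so there the test is undecided. The 6 include SERF1A and readthrough genes such as RAB4B-EGLN2 and CORO7-PAM16. No biological explanation was tested for these genes.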

How the results depend on the processing

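The inferred reads and the removal of genes with shared sequence were chosen after the data were seen. The median of the germ cell list (-1.08) turned to 0.80 at a minimum of 1 FPKM and to 1.46 with the mean, and that of the neuroectoderm list (-1.06) to 0.16 with no level minimum; both lists have few members that go both ways and stayed inside the limits for lists. No other result changed direction under the alternatives run. TFCP2L1 was at -2.94, at -1.66 with a pseudocount of 1 FPKM, at -3.27 in the authors' deposited table and at -3.27 from inferred reads. The 819 higher and 710 lower genes became 457 and 301 at a minimum of 5 FPKM, and 240 and 107 at a ratio of 4, where the stricter limit itself lowers the count. The lower genes numbered 364 with a pseudocount of 1 FPKM, and 424 with a counting interval beyond 2-fold. At a ratio of 1.5 the counts were 854 and 733, limited by the 2-fold minimum of the table.

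The limits for a list were the lowest and the highest 2.5% of random lists. The naive pluripotency list (1.94) came inside them with a pseudocount of 1 FPKM (1.13), no level minimum (1.54), a minimum of 1 FPKM (1.53) and the mean (1.20). The core and primed list (-1.21) passed them with a pseudocount of 1 FPKM (-1.17), with the log2 ratios of the authors' deposited table (-1.21) and without genes of shared sequence (-1.21), and stayed inside them in the other 5 settings. With the mean, Activin/NODAL targets (3.22) and the ER stress list (-1.40) passed them. The p53 targets (-1.45) came inside them against unmatched random lists. The cause was not tested. The streak, endoderm and WNT target lists stayed past the limits in each setting run. The streak list shares members with both others, and no setting left the shared members out. Of 147 other named genes, 47 moved by more than their counting interval with a pseudocount of 1 FPKM, 2 with the log2 ratios of the authors' deposited table and 3 with inferred reads. Genes with no scramble reads have an interval without an upper limit, so these counts do not show that their ratios are stable. SOX17 was not counted as moved, although its log2 ratio was 7.92, 4.77 with a pseudocount of 1 FPKM and 11.4 in the authors' deposited table.

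Dividing by the median ratio of expressed genes was not run, because the table holds only genes past 2-fold, and scalings of counts were not run, because it holds no counts. No paired analysis was possible because each group had 1 library. Genes with few reads are limited by depth, and the fewest over both libraries was 12.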

Other observations

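The gene groups in this part were chosen after values of their members had been seen, so their counts are descriptions and no independent evidence of a direction.

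FOXJ1, the transcription factor of motile ciliogenesis, was at 1.12 and 29.9 FPKM (ratio 26.8, interval 21.1 to 34.7). Of a list of 76 motile cilia genes, 32 were listed, 31 higher and 1 lower. The median log2 ratio was 2.04 over the 19 members at 0.5 FPKM or more, 1.78 over all 32, and 0.79 with a pseudocount of 1 FPKM. Values of 10 members, FOXJ1 among them, had been seen when the list was written. Of the other 66 members, 22 were listed, 21 of them higher, with a median log2 ratio of 2.04 at a percentile of 99.3 over the 16 at 0.5 FPKM or more, although this restriction was itself made after the result of the whole list was known. The outer arm dynein DNAH5 was at 0.08 and 1.36 FPKM (ratio 17.7, interval 12.1 to 26.9), the radial spoke gene RSPH4A at 0.05 and 1.42 FPKM, and TEKT2 at 0.55 and 4.16 FPKM. DNAH3 was the lower member, at 0.22 and 0.10 FPKM.

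Genes of the organizer and axial mesoderm overlapped the streak and endoderm lists. Of 17 such genes, 14 were listed and all 14 were higher, with a median log2 ratio of 5.98, or 3.88 with a pseudocount of 1 FPKM. SHH was at 0.02 and 6.11 FPKM, a ratio of 286 on 1 scramble read (interval 51.0 to 11356). NOTO, a notochord transcription factor, was at 0.04 and 2.85 FPKM, a ratio of 93.1 on 1 scramble read (interval 16.3 to 3717), and the activin antagonist FST was at 4.50 and 19.6 FPKM. Some other signalling genes were higher too, among them WNT8A (0.16 and 10.3 FPKM), BMP2 (0.27 and 6.67 FPKM) and the WNT receptors FZD2, FZD8 and FZD10. So was the retinoic acid hydroxylase CYP26A1 (2.59 and 77.0 FPKM, with 32.6% of its words in another gene). Others were lower, among them the FGF receptors FGFR2 (29.2 and 13.7 FPKM) and FGFR4 (42.0 and 19.9 FPKM). Of 8 listed genes with a WNT symbol, 6 were higher and 2 lower.

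Of 10 metallothionein genes, 5 were listed and all 5 were lower (median log2 ratio -1.85), with MT1X at 57.5 and 15.9 FPKM (ratio 0.278, interval 0.230 to 0.335) and MT1F at 16.5 and 7.08 FPKM. Their transcripts resemble each other, so reads can be split among them. The apoptosis gene PMAIP1 (239 and 50.6 FPKM) and the hexokinase gene HK1 (149 and 51.0 FPKM) were also lower. Of 33 listed zinc finger genes with a ZNF symbol, 29 were higher and 4 lower.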
